A study of Ovis aries with 12 samples.

How the data were processed

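RNA sequencing was analysed for 12 libraries of sheep oviduct epithelial cells, 3 at each of 4 times of oestradiol treatment (0, 1.5, 3.5 and 5.5 h). Per the labels, cells were scraped from the ampulla after trypsin, starved for 12 h and treated at 1e-08 M, and total RNA was taken with Trizol for Illumina libraries. The submitters' processing notes name TopHat2 2.0.9 and Cufflinks, without a role for either. The genome build and the counting tool are not given in the sources used here, and coordinates are those of the authors' tables.

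Per the file headers, the authors' deposited gene table gives a count and an FPKM value (fragments scaled to transcript length and library size) for each gene in each library. The authors' deposited comparison tables give a log2 ratio of the mean FPKM of each time to 0 h, with a p-value and a q-value from a test that is not stated. The authors' deposited enrichment tables give a p-value per term. A further 42 per-sample columns were not used here, and some terms and 1 gene are not reported here. Of 18340 genes, 4788 had no symbol in the table. A RefSeq name table (assembly ARS-UI_Ramb_v3.0), used for names alone, named 1145 of them, 3643 stayed under their Ensembl identifier, and 17 ambiguous names were skipped.

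Differences were tested on the counts with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Counts were scaled by TMM (factors 0.975 to 1.02), dispersions were estimated with a mean trend, and quasi-likelihood F tests were made in 1 model of the 4 times over all 12 libraries. The 12025 genes with a mean FPKM of at least 1 were tested, p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. The comparisons, the gene lists, the rule for named genes and the first set of other settings below were chosen before the data were examined, with limma on log2(FPKM + 1) as the test. Since counts were present, edgeR became the test, and limma was kept as an alternative. The 6 comparisons were each treated time with 0 h and the treated times with each other, together with a test among the 4 times. Values are given in CPM (counts scaled to the TMM-adjusted library size) as the mean ± SD of 3 libraries, and log2 differences with their standard error (SE). Principal components used log2 CPM with a prior count of 2.

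There were 25 gene lists, of which 24 had the 3 tested members needed. They held oestrogen receptors and partners, oestrogen targets, immediate early, MAPK feedback, NF-kB and cytokine, interferon-induced, antimicrobial and mucosal defence, heat shock, amino acid and ER stress, cholesterol synthesis, hypoxia and glycolysis, circadian clock, DNA replication, mitosis, ribosome biogenesis, TGF-beta and matrix, p53 and apoptosis and mitochondrially encoded genes. They also held markers of secretory oviduct, ciliated, general epithelial, fibroblast and stromal, smooth muscle, immune and endothelial cells. TAGLN stands in both the TGF-beta and the smooth muscle list. Lists were tested with camera at a preset correlation of 0.01 between members. The same test with the correlation estimated from the data, and fry, were run beside it. fry tests whether a list's members changed at all, and camera whether they changed more than other genes. No list call held with the estimated correlation or in fry in any of the 6 comparisons. With the replicate number as a block, fry passed circadian clock genes at 3.5 and 5.5 h against 0 h (adjusted p = 0.0416 and 0.0271).

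The genes named for each comparison were the called genes or, where none passed, the 5 with the smallest p. To these were added ESR1, ESR2, GPER1, PGR, GREB1, OVGP1, DEFB1, FOS, EGR1, MYC and FOXJ1 against 0 h. Members given as examples of a list, and genes called under other settings, were chosen after their values were seen.

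Numbers in the labels (1 to 3) were checked as pairs. Deviations from the group mean had correlations of 0.218 to 0.705 over the 18 pairs of libraries that share a number, and of −0.600 to 0.331 over the 36 pairs that do not. All 18 passed the limit of 0.1 set beforehand, so the numbers were used as a replicate block in an alternative and as pairs in the direction counts. Groups of 3 against 3 do not overlap in 10% of genes by chance. Libraries within a group differed well beyond counting error (chi-square per degree of freedom 34.9 to 267), and no pair of libraries was identical.

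The tests were tried on simulated data for 1.5 h against 0 h. Without the block, 47 of 100 genes changed 2-fold and 90 of 100 changed 4-fold were called, with 2 unchanged genes called. With the block the numbers were 76, 91 and 9. A changed list of 20 genes was called in both fits. The simulated genes varied independently of each other, and the data without the block carried no differences shared by libraries of the same number. These rates may therefore not hold for the real libraries. Correlations between comparisons that share the 0 h libraries were set against 20 simulations of unchanged groups (seed 1).

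Other settings chosen at that stage were a pseudocount of 0.1, no filter, a mean FPKM of at least 5 (8874 genes), median-of-ratios and quantile scaling, the replicate block, other variance estimates, a 2-fold minimum, a fit of only the 2 groups, the estimated correlation, and each library left out in turn. Pseudocount and quantile settings used limma on log2 FPKM, and median-of-ratios factors were computed on the counts. Fits with each library left out in turn had no block, so they left the numbers unequal between the times compared. DESeq2 1.42.0, the block without the 1.5 h library numbered 3, numbers 1 and 2 alone, and the estimated correlation with the block were chosen after seeing the data. limma on log2(FPKM + 1), first planned as the test, became an alternative once counts were found. Other splits of the libraries were counted for each comparison, all 10 for 3 against 3 and 100 drawn for the 4 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.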

Results

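Epithelial cells scraped from the mucosa of the sheep (Ovis aries) oviduct ampulla, the part of the tube where fertilisation takes place, were held for 12 h in medium without serum or phenol red, a dye with weak oestrogenic activity. They were then given 10 nM oestradiol (E2), the main ovarian oestrogen. RNA was sequenced at 0 h and after 1.5, 3.5 and 5.5 h, with 3 libraries at each time and 12 in all. Libraries without oestradiol after 0 h were not analysed here, so each difference from 0 h also holds the time spent in culture. Counts in genes summed to between 4.85e+07 (0 h, number 3) and 7.94e+07 (0 h, number 1) per library. At that depth the 3 counts taken as a detection floor came to 0.0378 to 0.0619 CPM, the count scaled to library size, which covers counting error only. The labels do not say whether the libraries came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

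The first principal component of log2 CPM held 44.1% of the variance and placed the libraries numbered 3 at 52.9 (0 h), 49.98 (3.5 h) and 57.1 (5.5 h), against −29.3 to −13.3 for the libraries numbered 1 and 2. The 1.5 h library numbered 3 stood apart from both sets, at 5.26 on that component and at 38.5 on principal component 3. Small nuclear RNA genes, a set that here also held signal recognition particle and RNase MRP RNA genes, also differed between libraries of 1 group. At 3.5 h they took 809 CPM in number 1 and 27.2 and 22.2 CPM in numbers 2 and 3, while at 0 h the values were 328, 369 and 54.2 CPM. Mitochondrially encoded genes took 4.83% to 6.04% of the counts.

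**Figure D1:**
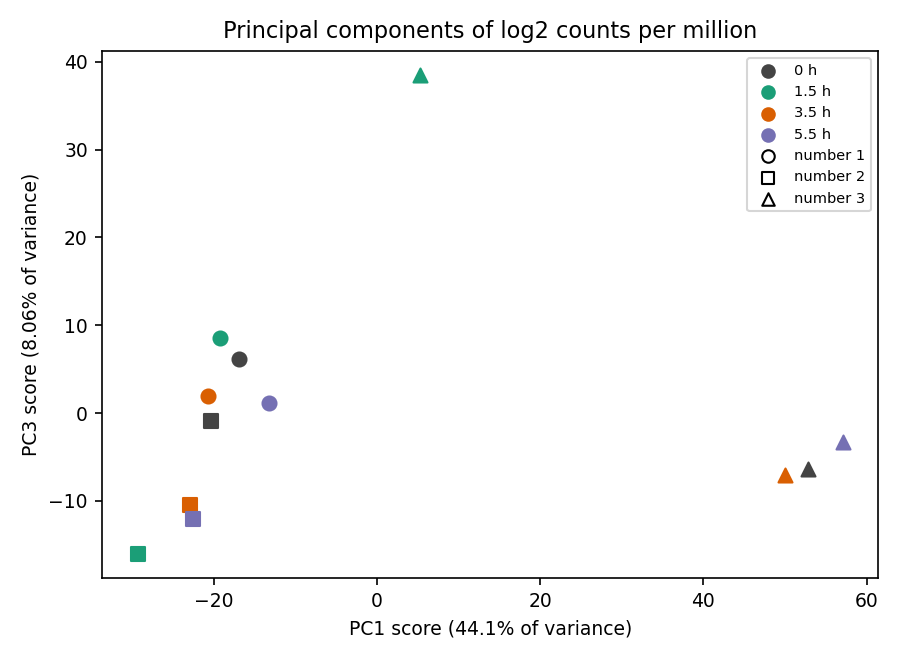
Position of the 12 libraries on principal components 1 (44.1% of the variance) and 3 (8.06%) of log2 CPM, with 1 point per library, coloured by time and shaped by the number in its label. The libraries numbered 3 at 0, 3.5 and 5.5 h lie at 49.98 to 57.1 on the first component, and the 1.5 h library numbered 3 lies at 5.26 there and at 38.5 on component 3.

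The oestrogen receptor gene ESR1 (ENSOARG00000003344), whose product binds oestradiol in the nucleus, was measured at every time. It averaged 11.7 ± 5.44 CPM at 0 h, 8.69 ± 1.97 at 1.5 h, 11.4 ± 2.86 at 3.5 h and 9.37 ± 1.23 at 5.5 h (SD, n = 3). The second nuclear receptor gene, ESR2, had 0 to 25 counts per library and was not tested, and GPER1 was not matched to a gene in the table. The progesterone receptor gene PGR (ENSOARG00000007837), a classical oestrogen target, averaged 12.2 ± 1.24 CPM at 0 h and 16.5 ± 0.477 at 5.5 h. The oviductin gene OVGP1, the beta-defensin gene DEFB1, the cilium regulator FOXJ1 and the oestrogen target GREB1 lay below the expression filter. They averaged 1.17 ± 0.216, 0.0437 ± 0.0757, 0.0663 ± 0.0763 and 4.38 ± 2.39 CPM at 0 h (SD, n = 3).

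The first comparison asked what differed after 1.5 h of oestradiol. Mitosis genes, which build the spindle and part the chromosomes, were lower than at 0 h in 24 of 25 measured members. The group fell by 0.85 on the log2 scale as a median (camera, adjusted p = 3.6e-09; adjusted p = 0.745 with an estimated correlation). MKI67, a marker of proliferating cells, averaged 40.2 ± 25.4 CPM against 102 ± 61.4 at 0 h (SD, n = 3), a log2 difference of −1.34 ± 0.98 (SE). TOP2A, which untangles DNA, CDK1, the kinase that starts mitosis, and CENPF, a kinetochore protein, lay at −1.17 ± 0.89, −1.06 ± 0.81 and −1.49 ± 0.97. The list median was lower in each same-numbered pair, at −0.49, −1.31 and −0.91 for numbers 1, 2 and 3, and stood at −0.37 without the 0 h library numbered 3 and at −0.53 without the 1.5 h library numbered 2. DNA replication genes fell as well, with 19 of 23 members lower and a median of −0.36 (camera, adjusted p = 0.00583; adjusted p = 0.776 with an estimated correlation). Among them were RRM2, a subunit of the enzyme that makes deoxynucleotides (−1.08 ± 0.97), the replicative helicase subunit MCM4 (−0.76 ± 0.69) and CDC45 (−0.93 ± 0.55). That call was lost without the 0 h library numbered 3 (adjusted p = 0.312, median −0.11), the 1.5 h library numbered 1 (0.0533) or the 1.5 h library numbered 2 (0.398, median −0.22). It was also lost at a mean FPKM of at least 5 (0.0808) and in limma with a pseudocount of 0.1 (0.0672) or 1 (0.0683). The median was −0.59 without the 1.5 h library numbered 3.

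Immediate early genes, which cells transcribe first after a stimulus, rose at 1.5 h by a median of 0.22, with 19 of 24 members higher (camera, adjusted p = 6.6e-06; adjusted p = 0.548 with an estimated correlation). FOSL1, a component of the AP-1 transcription factor, averaged 50.3 ± 7.16 CPM against 35.8 ± 1.38 (log2 difference 0.49 ± 0.12) and was the 1 member that passed when adjusted over the list alone (edgeR, adjusted p = 0.0491); 0 passed over all genes. JUN, IER3 and KLF4 lay at 0.35 ± 0.11, 0.62 ± 0.22 and 0.47 ± 0.18, while FOS, EGR1 and MYC lay at 0.20 ± 0.65, 0.20 ± 0.70 and −0.12 ± 0.31. NF-kB and cytokine genes, which take part in inflammation, rose by a median of 0.11 with 15 of 17 members higher (camera, adjusted p = 0.00583; adjusted p = 0.745 with an estimated correlation). RELB, an NF-kB subunit, and the cytokine gene LIF lay at 0.47 ± 0.18 and 0.30 ± 0.13. The NF-kB call was lost without the 0 h library numbered 2 (adjusted p = 0.0742, median 0.24) or 3 (0.0793), or the 1.5 h library numbered 1 (0.0615) or 2 (0.353). The median was 0.31 without the 0 h library numbered 1 and 0.25 without the 1.5 h library numbered 3.

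Smooth muscle markers rose at 1.5 h by a median of 1.17, with 4 of 4 members higher (camera, adjusted p = 3.9e-05; adjusted p = 0.548 with an estimated correlation). ACTA2, smooth muscle actin, averaged 30.0 ± 11.05 CPM against 12.2 ± 5.43, and CNN1, calponin, 72.9 ± 42.7 against 22.4 ± 19.5 (SD, n = 3). Fibroblast and stromal markers rose by a median of 0.51 in 7 of 7 members (camera, adjusted p = 0.00338; adjusted p = 0.745 with an estimated correlation), among them the collagen genes COL5A1 (1.12 ± 0.97) and COL3A1 (0.72 ± 0.83). TGF-beta and matrix genes rose by a median of 0.24, with 15 of 21 higher (camera, adjusted p = 0.0105; adjusted p = 0.745 with an estimated correlation). COL4A2, a basement membrane collagen, and TGFB2, a growth factor of that family, lay at 0.62 ± 0.39 and 0.55 ± 0.29. Antimicrobial and mucosal defence genes fell by a median of 0.45, with 8 of 12 lower (camera, adjusted p = 0.0142; adjusted p = 0.683 with an estimated correlation). S100A8 and S100A9, which form calprotectin, lay at −1.10 ± 0.56 and −0.89 ± 0.44.

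Much of the difference in these 4 groups lay in the libraries numbered 3. The pair medians for numbers 1, 2 and 3 were 0.46, 0.76 and 2.92 for smooth muscle markers and 0.07, −0.01 and 2.75 for fibroblast markers. For TGF-beta and matrix genes they were 0.08, 0.11 and 0.49, and for defence genes 0.05, 0.09 and −1.53. With the replicate number as a block and the 1.5 h library numbered 3 left out, a setting chosen after seeing the data, smooth muscle markers were still called, and fibroblast, TGF-beta and defence genes were not (camera, adjusted p = 0.564, 0.7501 and 0.797). With numbers 1 and 2 alone those 3 lists were not called either (0.820, 0.108 and 0.636). Without the 0 h library numbered 3 the fibroblast, TGF-beta and defence calls were lost (adjusted p = 0.332, 0.251 and 0.384) at medians of 0.20, 0.09 and −0.09. The TGF-beta call was also lost without the 1.5 h library numbered 1 (0.0533), with no filter (0.0662) and with quantile scaling (0.190). The defence call was also lost at a mean FPKM of at least 5 (0.0808), without the 1.5 h library numbered 3 (0.364) and under the replicate block (0.112). The median of the defence genes was −0.68 without the 0 h library numbered 1 or 2, and that of the fibroblast markers 0.84 without the 0 h library numbered 1.

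**Figure D2:**
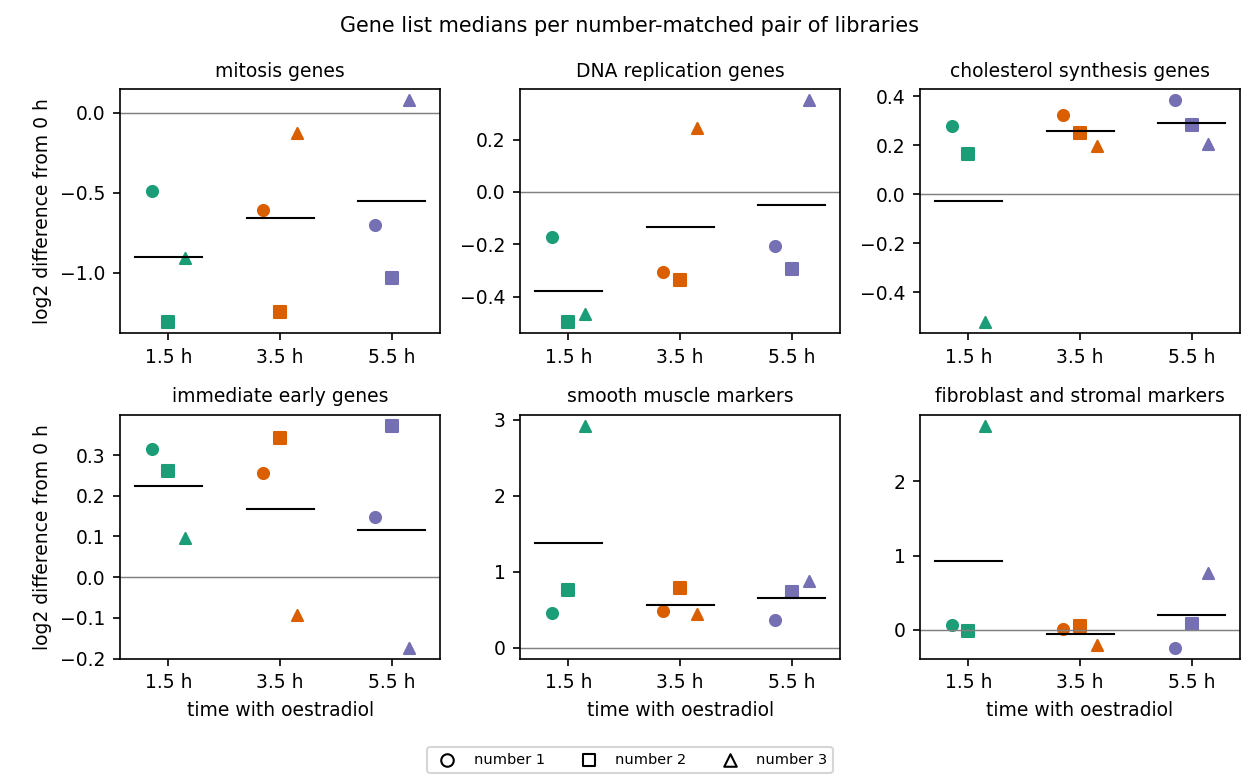
Median log2 difference from 0 h within each same-numbered pair of libraries (points, numbers 1 to 3) for 6 of the gene lists at 1.5, 3.5 and 5.5 h, with the mean of the 3 pair medians as a black bar. The mitosis medians lie below 0 in each pair except number 3 at 5.5 h (0.08), the cholesterol medians lie above 0 in each pair at 3.5 and 5.5 h, and the fibroblast median of pair 3 at 1.5 h lies at 2.75.

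The remaining lists did not pass at 1.5 h. Oestrogen target genes had a median of −0.01 over 20 members, with 10 higher and 10 lower (camera, direction up, adjusted p = 0.917; mean −0.11), and oestrogen receptors and partners a median of −0.09 over 10 members (adjusted p = 0.245). The adjusted p was 0.0788 for MAPK feedback genes, 0.245 for secretory oviduct epithelium markers and for p53 and apoptosis genes, 0.499 for endothelial markers and 0.527 for circadian clock genes and for hypoxia and glycolysis genes. It was 0.795 for amino acid and ER stress genes, 0.812 for cholesterol synthesis genes, and 0.917 for interferon-induced, heat shock, ribosome biogenesis and mitochondrially encoded genes and for ciliated and general epithelial markers. The pair medians of cholesterol synthesis genes at 1.5 h were 0.28, 0.17 and −0.52 for numbers 1, 2 and 3, so only pair 3 was lower than at 0 h. Immune cell markers had 2 measured members and were not tested. In all, 8 of 24 lists passed at 1.5 h, 5 up and 3 down, and 7 under the replicate block, none of them with an estimated correlation as well (smallest adjusted p = 0.439). The count was 5 without the 1.5 h library numbered 1.

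No single gene passed in edgeR at 1.5 h without the replicate block. Of 12025 genes, edgeR called 0, with 287 at an unadjusted p under 0.05 where 601 are given by chance, and DESeq2 called 1, CXCR4, or 96 with the replicate block, 40 up and 56 down. The fit without the block counts differences between numbers as spread, so the 287 do not show that genes stayed unchanged. CXCR4 (ENSOARG00000010462; chromosome 2, 173602065 to 173605247), the receptor of the chemokine CXCL12, had the smallest p. It averaged 167 ± 5.74 CPM against 82.2 ± 12.4 at 0 h (SD, n = 3) and was higher in 3 of 3 pairs (log2 difference 1.02 ± 0.16; edgeR, adjusted p = 0.601). With the replicate number as a block it was the 1 gene called (1.04 ± 0.095; edgeR, adjusted p = 0.00933), and 1180 genes had an unadjusted p under 0.05. The other 4 genes with the smallest p did not pass in edgeR with all 12 libraries, while DESeq2 with the replicate block called each of them (adjusted p = 2.0e-04 to 0.0339). With numbers 1 and 2 alone and the block, edgeR called SOD2 and ENSOARG00000005417 (adjusted p = 0.0205 and 0.0472). SOD2, the mitochondrial superoxide dismutase (ENSOARG00000004523; chromosome 8, 82622686 to 82631817), averaged 71.7 ± 9.72 against 121 ± 13.3 CPM, and TNS2 (ENSOARG00000016737; chromosome 3, 133238048 to 133250878), a focal adhesion protein, 18.8 ± 0.804 against 25.8 ± 1.36. TMEM129 (ENSOARG00000016060; chromosome 6, 116169873 to 116171606), a ubiquitin ligase of the endoplasmic reticulum, averaged 2.004 ± 0.192 against 9.92 ± 6.15 CPM, and the unnamed gene ENSOARG00000005417 11.4 ± 3.84 against 4.32 ± 0.578. Without the 1.5 h library numbered 3, edgeR called 1 gene, BCL2, an inhibitor of apoptosis that averaged 0.806 ± 0.161 CPM at 0 h. The 1.5 h libraries that remained both had 0 counts of it, so no fold is given.

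After 3.5 h the genes of cholesterol synthesis had the smallest camera p against 0 h, although not with the replicate block, where mitosis genes did. They rose by a median of 0.25 over 0 h, with 18 of 19 members higher and pair medians of 0.33, 0.25 and 0.20 (camera, adjusted p = 7.4e-07; adjusted p = 0.966 with an estimated correlation). Mevalonate kinase, MVK, averaged 32.4 ± 3.64 CPM against 24.6 ± 3.86 (SD, n = 3; log2 difference 0.40 ± 0.17, SE). SQLE and INSIG1 lay at 0.35 ± 0.21 and 0.35 ± 0.21. Immediate early genes rose by a median of 0.25, with 19 of 24 higher and pair medians of 0.25, 0.34 and −0.09 (camera, adjusted p = 5.3e-06; adjusted p = 0.966 with an estimated correlation). FOSL1, JUN, KLF4 and EGR2 lay at 0.35 ± 0.12, 0.29 ± 0.11, 0.48 ± 0.18 and 0.40 ± 0.17. FOS, EGR1 and MYC lay at 0.49 ± 0.65, 0.42 ± 0.70 and 0.16 ± 0.31. Mitosis genes fell by a median of 0.42, with 24 of 25 lower (camera, adjusted p = 3.1e-05; adjusted p = 0.966 with an estimated correlation). Their pair medians were −0.61, −1.25 and −0.12, and MKI67 averaged 70.1 ± 75.1 CPM against 102 ± 61.4.

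These 3 of 24 lists were the ones that passed at 3.5 h, 2 up and 1 down. With the replicate block 6 passed, adding circadian clock genes (adjusted p = 0.0378), DNA replication genes (0.0168) and smooth muscle markers (0.0378). With the block and an estimated correlation none of the 6 held (smallest adjusted p = 0.472). Without the block the medians of these 3 lists were 0.14, −0.05 and 0.67. The pair medians were 0.13, 0.04 and −0.0041 for the clock list, and −0.31, −0.34 and 0.25 for DNA replication genes, which lay higher in pair 3. TEF, a clock output transcription factor, averaged 15.9 ± 6.08 CPM against 7.65 ± 2.48 and was higher in 3 of 3 pairs. The cholesterol call was lost without the 0 h library numbered 2 (camera, adjusted p = 0.0952, median 0.14) or the 3.5 h library numbered 3 (0.0995, median 0.11), and the immediate early call without the 3.5 h library numbered 2 (0.115, median 0.15). The mitosis call was lost without the 0 h library numbered 3 (0.489, median 0.09) or the 3.5 h library numbered 1 (0.118, median −0.18) or 2 (0.563, median −0.06). The median was −1.38 without the 3.5 h library numbered 3 and −0.68 without the 0 h library numbered 2. These fits had no block, so leaving out a library also left the numbers unequal between the times. With the replicate block and all libraries the mitosis median was −0.69 (camera, adjusted p = 7.2e-24, or 0.472 with an estimated correlation). The cholesterol median was 0.47 without the 0 h library numbered 3 and 0.38 without the 3.5 h library numbered 2. The count of lists was 7 without the 0 h or the 3.5 h library numbered 3. Among the other lists, oestrogen target genes had a median of 0.03 and fibroblast markers one of −0.09 (camera, adjusted p = 0.946 and 0.770).

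edgeR called 0 of 12025 genes at 3.5 h, with 260 at an unadjusted p under 0.05, and DESeq2 called 6, or 34 with the replicate block. The replicate block also gave 0 in edgeR, with 782 at an unadjusted p under 0.05 where 601 are given by chance. The 5 genes with the smallest p, none of which passed in edgeR (adjusted p = 1.00) and each of which DESeq2 called with the block, included PARP12 (ENSOARG00000012408; chromosome 4, 103243956 to 103287653), an interferon-inducible ADP-ribosyltransferase. It averaged 24.1 ± 1.18 CPM against 32.4 ± 1.88 and was lower in 3 of 3 pairs (log2 difference −0.42 ± 0.10). TMEM129 averaged 1.70 ± 0.738 CPM against 9.92 ± 6.15 (−2.55 ± 0.56), and the unnamed gene ENSOARG00000013155 50.7 ± 10.3 against 80.4 ± 7.89 (−0.67 ± 0.14). A copy annotated as 60S ribosomal protein L9 (ENSOARG00000001382; chromosome 4, 110603406 to 110603984) averaged 25.8 ± 2.16 against 12.3 ± 1.74 (1.07 ± 0.21). A copy annotated as histone H3.3C (ENSOARG00000011310; chromosome 9, 32264801 to 32265308) averaged 65.3 ± 7.76 against 37.4 ± 10.96 (0.81 ± 0.19). Both belong to families of near-identical copies that can share reads, so their levels are uncertain.

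**Figure D3:**
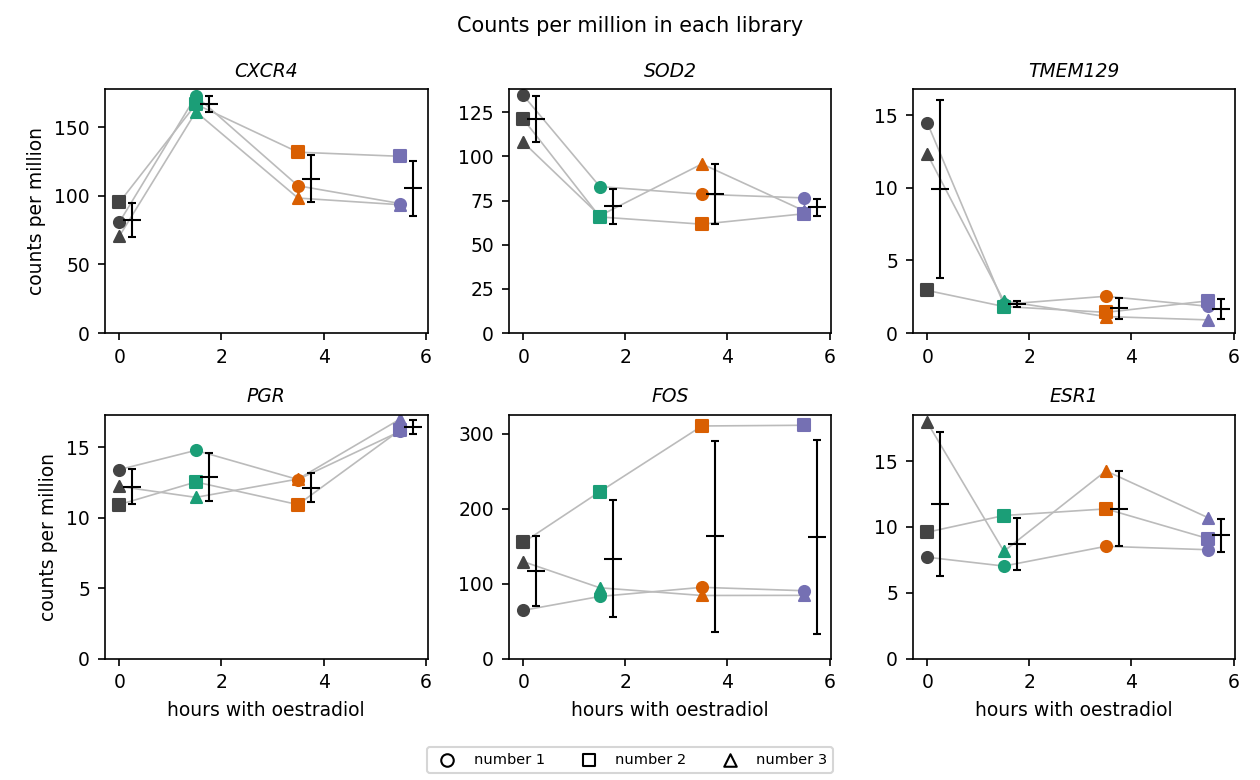
CPM of CXCR4, SOD2, TMEM129, PGR, FOS and ESR1 in each of the 12 libraries (points) by hours of oestradiol, with lines joining libraries that share a number and black marks for the mean ± SD of the 3 libraries at each time. CXCR4 averages 82.2 at 0 h and 167 at 1.5 h, SOD2 121 and 71.7, and PGR 12.2 at 0 h and 16.5 at 5.5 h.

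After 5.5 h cholesterol synthesis genes remained above 0 h, by a median of 0.30 with 17 of 19 members higher. They rose in each pair, with medians of 0.38, 0.28 and 0.21 (camera, adjusted p = 6.0e-08; adjusted p = 0.877 with an estimated correlation). HMGCS1, the first committed enzyme of the pathway, lay at 0.46 ± 0.31, the demethylase CYP51A1 at 0.41 ± 0.23, and ACAT2 averaged 339 ± 34.5 CPM against 272 ± 46.1 (0.32 ± 0.13). Immediate early genes rose by a median of 0.17, with 20 of 24 higher and pair medians of 0.15, 0.37 and −0.17 (camera, adjusted p = 0.00173; adjusted p = 0.877 with an estimated correlation). MAPK feedback genes, which restrain the signalling that induces them, rose by a median of 0.10 in 9 of 13 members (camera, adjusted p = 0.0300; adjusted p = 0.877 with an estimated correlation). The phosphatase genes DUSP5 and DUSP4 lay at 0.50 ± 0.16 and 0.46 ± 0.19. Mitosis genes fell by a median of 0.26, with 23 of 25 lower (camera, adjusted p = 0.00173; adjusted p = 0.900 with an estimated correlation). The pair medians were −0.70, −1.03 and 0.08. PGR averaged 16.5 ± 0.477 CPM against 12.2 ± 1.24 (SD, n = 3) and was higher in 3 of 3 pairs (log2 difference 0.43 ± 0.13), but did not pass over all genes (edgeR, adjusted p = 1.00) or adjusted over the list alone (0.167).

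With the replicate block 6 of 24 lists passed at 5.5 h against 4 without, 3 up and 1 down. The block added circadian clock genes (adjusted p = 0.0237) and smooth muscle markers (0.0199), with medians of 0.08 and 0.62 without the block. With the block and an estimated correlation none of the 6 held (smallest adjusted p = 0.544), and the pair medians of the clock list were 0.09, 0.16 and −0.11. TEF and CRY1, both of the clock list, lay at 0.97 ± 0.38 and 0.38 ± 0.20, and ACTA2 and SYNPO2 at 0.60 ± 0.57 and 0.65 ± 0.58. The mitosis call was lost without the 0 h library numbered 3 (camera, adjusted p = 0.899, median 0.20) or the 5.5 h library numbered 1 (0.336, median 0.00) or 2 (0.930, median 0.13), and its median was −1.38 without the 5.5 h library numbered 3. It was −0.42 and −0.45 without the 0 h libraries numbered 1 and 2. With the replicate block and all libraries the mitosis median was −0.54 (camera, adjusted p = 7.2e-17, or 0.544 with an estimated correlation). The immediate early call was lost without the 0 h library numbered 1 (0.0542) or the 5.5 h library numbered 2 (0.732, median 0.03), with a median of 0.27 without the 5.5 h library numbered 3. The MAPK feedback call was lost without the 0 h library numbered 1 (0.0547) or 3 (0.189) or the 5.5 h library numbered 1 (0.257, median 0.04) or 2 (0.404, median −0.01), and the median was 0.20 without the 5.5 h library numbered 3. It was also lost at a mean FPKM of at least 5 (0.0503), with quantile scaling (0.0787), in limma with a pseudocount of 0.1 (0.0524) or 1 (0.0602), and under the block without the 1.5 h library numbered 3 (0.0645). The cholesterol median was 0.17 without the 0 h library numbered 2, 0.45 without the 0 h library numbered 3 and 0.13 without the 5.5 h library numbered 3. The count of lists was 2 without the library numbered 1 of 0 h or of 5.5 h, 7 without the 0 h library numbered 2 and 9 without the 5.5 h library numbered 3. Oestrogen target genes had a median of −0.03 (camera, direction up, adjusted p = 0.730).

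edgeR called 0 genes at 5.5 h, with 252 at an unadjusted p under 0.05, and DESeq2 called 7, or 32 with the replicate block. The block gave 0 in edgeR as well, with 783 at an unadjusted p under 0.05, 404 higher and 379 lower, against 144 and 108 without it. None of the 5 genes with the smallest p passed in edgeR (adjusted p = 0.999 to 1.00), and DESeq2 called each of them. SOD2 averaged 71.1 ± 4.78 CPM against 121 ± 13.3 and was lower in 3 of 3 pairs (log2 difference −0.77 ± 0.16), and TMEM129 averaged 1.65 ± 0.676 against 9.92 ± 6.15 (−2.58 ± 0.56). ENSOARG00000004160 (chromosome 26, 20779381 to 20779845), annotated as human C16orf87, averaged 19.1 ± 1.46 against 12.5 ± 0.540 (0.61 ± 0.12). The 60S ribosomal protein L9 copies ENSOARG00000001382 and ENSOARG00000020156 lay at 1.28 ± 0.21 and 2.46 ± 0.51, with the same uncertainty over shared reads. FOS, EGR1 and MYC lay at 0.48 ± 0.65, 0.31 ± 0.70 and 0.02 ± 0.31. With numbers 1 and 2 alone and the block, edgeR called FOS at 5.5 h (0.75; adjusted p = 0.0435), while its pair 3 lay at −0.61 and it did not pass with the block over all 12 libraries (adjusted p = 0.897). Without the 5.5 h library numbered 1, edgeR called 1 gene, the unnamed ENSOARG00000025639, which had 0 counts in both 5.5 h libraries that remained.

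The times of treatment were also compared with each other. Cholesterol synthesis genes were higher at 3.5 h than at 1.5 h in 19 of 19 members, a rise of 0.30 in the median (camera, adjusted p = 2.5e-08; adjusted p = 0.993 with an estimated correlation). Most of that rise lay in the libraries numbered 3, with pair medians of 0.035, 0.12 and 0.64, and the median was 0.08 with numbers 1 and 2 alone (adjusted p = 0.0459). From 1.5 to 3.5 h defence genes rose by a median of 0.36, and fibroblast, smooth muscle and TGF-beta genes fell by 0.60, 0.60 and 0.14 (camera, adjusted p = 0.0201, 1.9e-04, 0.0231 and 0.0456). With an estimated correlation none of these held (adjusted p = 0.919 to 0.993). All 4 differences lay in the libraries numbered 3, with pair medians of 0.02, −0.04 and 1.39 for defence, −0.08, 0.03 and −2.36 for fibroblast, −0.02, 0.05 and −2.38 for smooth muscle and 0.02, 0.00 and −0.51 for TGF-beta genes. With numbers 1 and 2 alone none passed (adjusted p = 0.670, 0.703, 0.983 and 0.983), and the direction turned for all but the fibroblast markers. The block kept 5 lists, without the defence and TGF-beta calls (adjusted p = 0.0560 for both) and with mitosis genes (adjusted p = 3.6e-04) and DNA replication genes (0.00317) added, none of which held with the block and an estimated correlation (smallest adjusted p = 0.718). Without the block these lists had medians of 0.47 and 0.32 and did not pass (adjusted p = 0.0547 and 0.0539). From 1.5 to 5.5 h 7 lists passed, 3 up and 4 down. Cholesterol synthesis, mitosis and DNA replication genes rose by 0.31, 0.56 and 0.43, and NF-kB, TGF-beta, fibroblast and smooth muscle genes fell by 0.13, 0.29, 0.59 and 0.62 (camera, adjusted p = 1.8e-08 to 0.0419; adjusted p = 0.873 with an estimated correlation). With numbers 1 and 2 alone only the cholesterol and NF-kB calls held, at medians of 0.10 and −0.12, while mitosis, DNA replication and smooth muscle genes had medians of −0.016, 0.10 and −0.0043 (adjusted p = 0.930, 0.511 and 0.930). From 3.5 to 5.5 h 0 of 24 lists passed, and the smallest adjusted p was 0.139, for TGF-beta and matrix genes (camera; median −0.09).

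Leaving out the 1.5 h library numbered 3 ended the defence, TGF-beta and smooth muscle calls between 1.5 and 3.5 h (camera, adjusted p = 0.268, 0.103 and 0.104) and the fibroblast and smooth muscle calls between 1.5 and 5.5 h (0.0611 and 0.190). Leaving out the 3.5 h library numbered 3 ended all but the cholesterol call between 1.5 and 3.5 h (0.234 to 0.6996). The medians shrank to 0.09 for defence, −0.04 for TGF-beta, −0.20 for fibroblast and −0.22 for smooth muscle genes. Without the 5.5 h library numbered 3 the mitosis call between 1.5 and 5.5 h turned round, with a median of −0.46 and a fall that passed (camera, adjusted p = 6.3e-04). That fit had no block, and the numbers were unequal between the times with the 5.5 h library numbered 3 left out. Without that library, the NF-kB, DNA replication, TGF-beta, fibroblast and smooth muscle calls between 1.5 and 5.5 h were lost (0.121 to 0.420), with a median of −0.16 for DNA replication. Without the 1.5 h library numbered 2, the NF-kB, DNA replication, mitosis and smooth muscle calls of that comparison were lost (0.398 to 0.875), at medians of −0.03, 0.26, 0.27 and −0.60. Smooth muscle markers also lost their call between 1.5 and 3.5 h without the 1.5 h library numbered 2 (0.233, median −0.58) or the 3.5 h library numbered 1 (0.0821, median −0.55), and between 1.5 and 5.5 h without the 5.5 h library numbered 1 (0.204, median −0.54). TGF-beta genes lost theirs between 1.5 and 3.5 h without the 1.5 h library numbered 1 (0.165, median −0.16) or 2 (0.0641, median −0.12). Cholesterol synthesis genes kept both calls, at medians of 0.11 without the 3.5 h library numbered 3 and 0.17 without the 5.5 h library numbered 3.

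Processing also ended calls between treated times. From 1.5 to 3.5 h the defence call was lost at a mean FPKM of at least 5 (camera, adjusted p = 0.0539, median 0.40). The TGF-beta call was lost with no filter (0.202), quantile scaling (0.197) and limma with a pseudocount of 0.1 (0.0988) or 1 (0.0789), and the smooth muscle call with quantile scaling (0.0792) and limma with a pseudocount of 0.1 (0.0535). The smooth muscle medians in those 2 settings were −0.74 and −0.76, against −0.60 in edgeR, so the difference did not shrink. From 1.5 to 5.5 h the mitosis, DNA replication and smooth muscle calls were lost at a mean FPKM of at least 5 (0.0628, 0.105 and 0.0628). They were also lost in limma with a pseudocount of 0.1 (0.301, 0.0697 and 0.0697) and of 1 (0.208, 0.0578 and 0.0578). With quantile scaling the mitosis and smooth muscle calls were lost (0.167 and 0.117).

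Other calls between treated times held and changed in size with 1 library. From 1.5 to 3.5 h the defence genes had medians of 0.64, 0.58 and 0.61 without the 1.5 h library numbered 1, the 3.5 h library numbered 1 and the 3.5 h library numbered 2. Without the 3.5 h library numbered 1 the medians of TGF-beta genes and fibroblast markers were −0.26 and −1.01, and without the 3.5 h library numbered 2 those of TGF-beta genes and smooth muscle markers were −0.27 and −1.20. From 1.5 to 5.5 h mitosis genes had medians of 1.07, 0.85 and 0.98 without the 1.5 h library numbered 3, the 5.5 h library numbered 1 and the 5.5 h library numbered 2. Without the 5.5 h library numbered 2 the DNA replication, NF-kB and smooth muscle medians were 0.64, −0.28 and −1.14, and without the 1.5 h library numbered 3 the NF-kB median was −0.28.

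edgeR called 0 genes in each comparison between treated times. At an unadjusted p under 0.05 there were 161 between 1.5 and 3.5 h, 92 between 3.5 and 5.5 h and 210 between 1.5 and 5.5 h (616, 266 and 972 with the replicate block), and DESeq2 called 3, 1 and 2, or 7, 4 and 9 with the replicate block. CXCR4 averaged 106 ± 20.1 CPM at 5.5 h against 167 ± 5.74 at 1.5 h, lower in 3 of 3 pairs (log2 difference −0.66 ± 0.16; edgeR, adjusted p = 1.00). The ribosomal protein L9 copy ENSOARG00000001382 had the smallest p from 1.5 to 5.5 h (1.53 ± 0.21; edgeR, adjusted p = 0.218) and was the 1 gene called with the replicate block (1.51 ± 0.16; adjusted p = 0.0286). INTS6L, annotated as DDX26B, C12orf49 and the unnamed ENSOARG00000003385 lay at 0.84 ± 0.22, −0.48 ± 0.13 and 0.59 ± 0.15 over the same interval. From 1.5 to 3.5 h that L9 copy lay at 1.32 ± 0.21, a ribosomal protein L7-like copy (ENSOARG00000010153) at 1.00 ± 0.23, the small GTPase gene RASL11B at −0.74 ± 0.20, and the unnamed ENSOARG00000015758 and ENSOARG00000005189 at −0.48 ± 0.11 and −2.30 ± 0.55. From 3.5 to 5.5 h the L7-like copy and the unnamed ENSOARG00000006035 and ENSOARG00000013155 lay at −0.93 ± 0.23, −1.06 ± 0.26 and 0.49 ± 0.14. The unnamed ENSOARG00000021319 lay at −4.23 ± 1.15, but at −0.83 without the 3.5 h library numbered 1, which carried most of its 16.8 ± 26.4 CPM at 3.5 h. The small RNA gene RF02153 averaged 3.17 ± 0.515 CPM at 5.5 h and 0.0383 CPM at 3.5 h, below the 3-count floor of those libraries (0.0544 to 0.0605 CPM).

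Those counts moved with single libraries. Without the 1.5 h library numbered 3, edgeR called 1 gene (BCL2) between 1.5 and 3.5 h and between 1.5 and 5.5 h. Without the 5.5 h library numbered 1 it called 1 gene (ENSOARG00000025639) between 3.5 and 5.5 h and 2 (ENSOARG00000025639 and ENSOARG00000001382) between 1.5 and 5.5 h. With only the 2 groups compared it called 1, RF02153, between 3.5 and 5.5 h. Over all 4 times together edgeR called 0 genes, with 147 at an unadjusted p under 0.05 (657 with the replicate block), against 6 by DESeq2 and 76 by DESeq2 with the replicate block, 2 with the replicate block (CXCR4 and ENSOARG00000001382) and 2 without the 5.5 h library numbered 1 (ENSOARG00000001382 and ENSOARG00000025639).

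The 3 differences from 0 h were then set against each other over 12025 genes. Across genes, which are not independent replicates, log2 changes at 3.5 and 5.5 h had a correlation of 0.476 and the same sign in 74.96% of genes. For 1.5 and 3.5 h the values were 0.324 and 66.5%, and for 1.5 and 5.5 h 0.432 and 63.5%. All 3 comparisons share the 0 h libraries, and in 20 simulations of 12 unchanged libraries with the same pairing the mean correlations were 0.504, 0.507 and 0.521, with the same sign in 66.6%, 66.6% and 66.7% of genes. The observed covariance was 0.0426, 0.0323 and 0.0391, against 0.0457, 0.0457 and 0.0468 simulated, so all 3 lay below the simulated mean (difference −0.00304, −0.0134 and −0.00769). The simulated covariances had an SD of 0.00541, 0.00539 and 0.00516, so the first difference lay within 1 SD. Genes were drawn independently of each other there, so this spread may not hold for the real libraries. With 3 libraries the 0 h group could not be split with 2 libraries in each part. The number of genes called in a pair of comparisons together was 0, and 0 were expected of independent lists.

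The authors' deposited tables give their own comparison of each time with 0 h. The authors' deposited table for 1.5 h marks 43 genes as up and 80 as down, of which 3 had a q under 0.05, with CXCR4 at a log2 fold change of 0.99 and TMEM129 at −2.36 among them. The authors' deposited table for 3.5 h marks 59 genes, 28 up and 31 down, with 7 at a q under 0.05, and that for 5.5 h 46 genes, 21 up and 25 down, with 5. GJA5, the gap junction protein connexin 40, stands in the authors' deposited tables at a log2 fold change of 1.38 at 3.5 h (q = 0.0322) and 1.64 at 5.5 h (q = 0.0225). Of the genes the authors' deposited tables mark, 89, 49 and 39 were among those tested here at 1.5, 3.5 and 5.5 h. All of them had the same direction here, and 24, 30 and 17 had an unadjusted p under 0.05 in edgeR. Both comparisons use the same libraries, and nearly all marked genes differed by at least 2-fold in them. The shared direction was therefore close to fixed in advance and is no independent evidence. The first terms in the authors' deposited enrichment tables for gene ontology were RAGE receptor binding at 1.5 h, with S100A8, S100A9 and S100A12 down, and toxin metabolic process at 3.5 h, with CYP1A1, CYP1A2 and CYP1B1 up. At 5.5 h the first term in the authors' deposited gene ontology table was extracellular region, with 3 of its 8 genes up and 5 down.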

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

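In this part the tests of the label, of mixing, of cell types, of the small nuclear RNA batch, of members that vary together and of time in culture were chosen only after the result was seen. The length trend and the splits of the libraries were planned. The estimated correlation without the block was planned as a setting, and its use to weigh members that vary together came afterwards.

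A difference between treated times was found in 12 list comparisons by a direct test (camera, 3 libraries a group). Between 1.5 and 3.5 h these were the antimicrobial defence (adjusted p = 0.0201), cholesterol synthesis (2.5e-08), TGF-beta and matrix (0.0456), fibroblast (1.9e-04) and smooth muscle (0.0231) lists. Between 1.5 and 5.5 h they were the NF-kB (0.00461), cholesterol synthesis (1.8e-08), DNA replication (0.00461), mitosis (0.0109), TGF-beta and matrix (1.1e-04), fibroblast (0.00461) and smooth muscle (0.0419) lists. None held with an estimated correlation (adjusted p = 0.873 to 0.993). With numbers 1 and 2 alone, a setting chosen after the data were seen, only both cholesterol synthesis calls and the NF-kB call held. The ribosomal protein L9 copy ENSOARG00000001382 was lower than at 0 h in each pair at 1.5 h and higher in each pair at 3.5 and 5.5 h. That rule compares signs, so a difference between the times was not tested by it. In direct tests the log2 differences from 1.5 h were 1.32 and 1.53 and did not pass (edgeR, adjusted p = 0.766 and 0.218). With the replicate block the adjusted p was 0.0874 and 0.0286, so 5.5 h was called there.

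The first pattern weighed was the 1.5 h library numbered 3, which lay apart from the other libraries numbered 3. An exchange of its label with that of a library numbered 1 or 2 is argued against, since none of those 8 libraries resembled number 3. On the first principal component, which uses no chosen genes, they lay at −29.3 to −13.3. The other libraries numbered 3 lay at 49.98 to 57.1 there, and the 1.5 h library numbered 3 at 5.26. The median position of that library over 208 genes was 0.284, on a scale of 0 for numbers 1 and 2 and 1 for number 3, while those 8 libraries reached at most 0.0752. The 208 genes were chosen to part those 8 from the other libraries numbered 3, which narrows their range, so this position alone could hide a partner. RNA of another culture mixed into the 1.5 h library numbered 3 stays open, as the shares of number 3 RNA needed by genes high in either set, 0.210 and 0.392, differed by 0.182 and both varied widely between genes. A higher share of stromal or smooth muscle cells may contribute, as 72.7% of the markers (8 of 11) were higher there than in any other library, among them CNN1 (117 against 73.2 CPM) and COL5A1 (23.9 against 12.3). The exceptions were VIM (2140 against 2710 CPM), COL1A2 (15.8 against 17.9) and SYNPO2 (34.8 against 58.8), and cultured epithelial cells can express VIM and TAGLN as well. CNN1 and COL5A1 had the largest excesses, while COL1A1, FBLN1, ACTA2, TAGLN and THY1 lay 1.08 to 1.23 times above the next library. The fibroblast list median there was 1.13 relative to 0 h (log2), against at most 0.86 in numbers 1 and 2 and −1.62 to −0.61 in the other libraries numbered 3. For smooth muscle markers these were 1.79, 1.57 and −1.13 to −0.28.

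The next pattern was the fall of mitosis genes. A library batch seen in the small nuclear RNA counts stays open. The list median averaged −0.579 over 7 pairs within a batch, but these pairs share 3 libraries of 0 h, and the mean over the 3 numbers was −0.741 with a 95% t interval of −2.01 to 0.528. Members that vary together between cultures may account for the size of the camera p, since the smallest adjusted p with an estimated correlation was 0.439 over the 3 times, with and without the block. Time in culture cannot be told apart from oestradiol, since the number of libraries without oestradiol after 0 h analysed here was 0.

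The last pattern was the rise of cholesterol synthesis genes at 3.5 and 5.5 h. The list median was higher than at 0 h in 4 of 4 pairs within a small nuclear RNA batch. Its mean was 0.278 there and 0.275 over all 6 pairs, so the rise was no smaller within a batch. These 4 pairs rest on 2 libraries of 0 h, with a 95% t interval over the 2 numbers of −0.695 to 1.25. An interval over 2 numbers is too wide to decide, so a batch stays open. A trend with transcript length is argued against as the whole cause, since the trend fitted over all tested genes reached at most 0.060 and 0.044 at 3.5 and 5.5 h, against list medians of 0.25 and 0.30. With so small a trend removed, 97.2% and 95.2% of those medians were kept. Time in culture cannot be told apart from oestradiol here either, again with 0 libraries without oestradiol after 0 h.

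The 6 libraries of a comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes called, the real value was 0 in each of the 6 comparisons, so all 10 splits gave as many, and the highest other value was 1, 0 and 1 against 0 h at 1.5, 3.5 and 5.5 h, and 1, 1 and 0 between 1.5 and 3.5 h, 3.5 and 5.5 h, and 1.5 and 5.5 h. For lists the real values were 8, 3 and 4 against 0 h, the highest others were 10, 16 and 14, and 5, 8 and 8 splits gave as many, the real one included. Among the 3 other splits that part each pair, which mix times within a side, the highest were 8, 12 and 11. Among the 4 times all 100 of the 100 splits gave as many genes as the real 0, and the highest other called 5110, which points to the structure of the samples. It was the 1 drawn split that put the 0, 3.5 and 5.5 h libraries numbered 3 in 1 group, with 3 libraries numbered 1 and 3 numbered 2 in groups of their own, and no other split called more than 2.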

How the results depend on the processing

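Settings with DESeq2, with numbers 1 and 2 alone, with the 1.5 h library numbered 3 left out under the block, and with the estimated correlation together with the block were chosen after seeing the data. limma on log2(FPKM + 1), first planned as the test, became an alternative once counts were found. Over all settings, 158 counts stayed within 1.5 times and 54 moved, and of the values of named genes 854 kept direction and side of the threshold, 46 passed the threshold and 39 reversed. Of the list medians, compared under median-of-ratios and quantile scaling alone, 140 stayed within 1 SD of the pair medians and 4 moved, and the report gives their larger moves under other settings. That SD is wide where the pairs differ. Defence genes counted as unmoved with medians of −0.455 and −0.193 at 1.5 h and of −0.299 and −0.018 at 5.5 h under these scalings. Beyond what is given in the report, the replicate block changed no other call. TMEM129, TNS2, INTS6L and ENSOARG00000005189 had no value at a mean FPKM of at least 5. Depth set a floor of 0.0378 to 0.0619 CPM for 3 counts in a library, and genes near it have no reliable fold. For each value below the cause was not tested.

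Genes called moved from 0 as follows, in the order 1.5, 3.5 and 5.5 h against 0 h, 3.5 against 1.5 h, 5.5 against 3.5 h, 5.5 against 1.5 h and among the 4 times. DESeq2 called 1, 6, 7, 3, 1, 2 and 6, and with the block 96, 34, 32, 7, 4, 9 and 76. The edgeR block called 1 at 1.5 h, 1 for 5.5 against 1.5 h and 2 among the 4 times. With the 1.5 h library numbered 3 left out as well, 4, 12, 1 and 3 were called at 1.5 h, at 5.5 h, for 3.5 against 1.5 h and among the 4 times. Numbers 1 and 2 with the block called 21, 28, 71, 1 (5.5 against 1.5 h) and 30 (4 times), and without it 1 at 5.5 h. Only the 2 groups compared gave 1 for 5.5 against 3.5 h. Leaving out 1 library gave 0 to 1 at 1.5 h, 5.5 h, 3.5 against 1.5 h and 5.5 against 3.5 h, and 0 to 2 for 5.5 against 1.5 h and among the 4 times.

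Lists called were 0, 0 and 0 at 1.5, 3.5 and 5.5 h with the estimated correlation, and 0, 0 and 0 with the block added. At 3.5 h the block gave 6, the block without the 1.5 h library numbered 3 gave 5, and numbers 1 and 2 gave 10 without and 10 with the block. At 5.5 h the last pair of settings gave 10 and 11. Leaving out 1 library gave 5 to 10, 2 to 7 and 2 to 9.

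Log2 differences of genes that did not pass with all 12 libraries in edgeR reversed as follows. Numbers 1 and 2 alone gave ESR1 0.050, 0.21 and 0.011 at 1.5, 3.5 and 5.5 h and MYC 0.053 at 1.5 h, and with the block 0.031, 0.20, 0.021 and 0.034. The block without the 1.5 h library numbered 3 gave MYC 0.029 at 1.5 h, ESR1 0.0062 at 3.5 h and EGR1 −0.017 at 5.5 h. Quantile scaling gave ESR1 0.022 and PGR 0.0051 at 3.5 h and EGR1 −0.018 at 5.5 h. EGR1 at 5.5 h was −0.014 with the block, −0.018 with DESeq2 and the block, −0.016 with a pseudocount of 0.1 and −0.012 with limma on log2(FPKM + 1). Leaving out 1 library gave, at 1.5 h, ESR1 −0.67 to 0.0039, PGR −0.024 to 0.16, FOS −0.39 to 0.46, EGR1 −0.40 to 0.60 and MYC −0.27 to 0.18. At 3.5 h it gave ESR1 −0.27 to 0.40, PGR −0.080 to 0.066, FOS −0.37 to 0.80, EGR1 −0.46 to 0.82 and MYC −0.19 to 0.45. At 5.5 h it gave ESR1 −0.56 to 0.11, FOS −0.41 to 0.79, EGR1 −0.81 to 0.71 and MYC −0.20 to 0.31.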

Other observations

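The genes and the list in this part were chosen only after the result was seen. CYP1A1, a monooxygenase gene induced by the aryl hydrocarbon receptor, which senses dioxins and plant indoles, did not pass the test. It averaged 6.33 ± 4.11 CPM at 0 h and 19.8 ± 9.21, 15.9 ± 6.74 and 11.8 ± 6.55 at 1.5, 3.5 and 5.5 h (SD, n = 3). The log2 difference at 1.5 h was 1.64 ± 0.63 (SE; edgeR, adjusted p = 1.00). CYP1A2 averaged 2.23 ± 1.12 CPM at 0 h and 7.19 ± 3.24, 6.69 ± 1.30 and 3.96 ± 2.72 afterwards, and CYP1B1 9.13 ± 7.99 and then 29.1 ± 11.8, 18.2 ± 14.7 and 11.1 ± 7.77. TIPARP, a receptor target that is also in the oestrogen target list, averaged 288 ± 39.5 at 0 h and 396 ± 68.3, 307 ± 38.2 and 300 ± 15.9 afterwards. NQO1, another target, went the other way, at 8.04 ± 2.34 and then 5.65 ± 1.58, 7.22 ± 0.514 and 7.45 ± 1.10. These genes were picked by their values, so no test of the group was made.

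Some genes outside the lists lay on the same side of 0 h in each pair, without passing the test over all genes. TGM2, tissue transglutaminase, averaged 1190 ± 455 CPM at 0 h and 710 ± 158, 663 ± 169 and 605 ± 180 at 1.5, 3.5 and 5.5 h. TNFAIP8L3, a phosphoinositide transfer protein, averaged 19.7 ± 6.05 CPM at 0 h and 33.2 ± 8.89 at 5.5 h (log2 difference 0.75 ± 0.26). With numbers 1 and 2 alone and the replicate block, edgeR called the gap junction gene GJA5 at all 3 times (log2 differences 1.87, 1.70 and 2.17), the hyaluronidase CEMIP (1.08, 1.07 and 1.25) and the basal keratin KRT5 (1.06, 1.09 and 1.04). These calls come from 2 libraries a group, and edgeR called none of the 3 genes with all 12 libraries, while DESeq2 with the replicate block called CEMIP at 3.5 and 5.5 h.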
